A study of Mus musculus with 2 samples.

How the data were processed

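The data were 10x Genomics 3' v3 single-cell libraries of unsorted cells from the tendon injury site of male C57BL/6 mice aged 8 to 10 weeks. Per the labels, mice had a burn of 30% of the body surface with Achilles tendon transection, and the site was collected 7 days later. Irradiated mice had received a single dose of 7 Gy through a collimator of 2 cm. Tissue was digested with collagenase and dispase, and viability was above 85%. The labels describe treatment arms of 10 mice irradiated on postoperative day 1 or 3. The series description points to day 3 for the irradiated library, in wording that leaves the day uncertain. How many mice were pooled in each library is not stated. There is 1 library per group, so library and treatment cannot be separated.

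The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 5 against mm10 (version 5.0.1 per the file headers), with no normalisation. Barcodes had been called as cells by the authors and the lowest total was 500 UMIs. Further filters by the authors are not stated. The feature list of 32285 genes was the same in both libraries, and 26688 genes had at least 1 UMI. Gene positions came from GENCODE M21 (GRCm38, the same assembly as mm10), matched by gene ID for 457 of 457 genes sought.

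Gene lists, cell type markers, filters, size rules and most alternatives were fixed before the data were examined. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. In the control library 1076 barcodes lay below the gene minimum, 718 below the UMI minimum and 1693 above the mitochondrial limit, 758 of them above 50% mitochondrial UMIs. In the irradiated library these numbers were 664, 501, 509 and 107. Doublets were called in each library with Scrublet in scanpy 1.11.5 (anndata 0.12.19, Python 3.11.15) and left out. Its automatic score threshold differed, 0.230 in the control and 0.410 in the irradiated library, so it called 596 doublets (5.24%) and 47 (0.566%), against expected rates of 9.10% and 6.64%. An equal threshold was therefore added as an alternative. The kept cells were 76.5% of control barcodes (median 13217 UMIs) and 86.1% of irradiated barcodes (median 10156 UMIs).

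Both libraries were clustered together without integration: counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes among those seen in at least 10 cells were reduced to 30 principal components. A shared-neighbour graph of 15 neighbours was split by the Leiden method (leidenalg 0.10.2, igraph 0.11.9, resolution 1.0, seed 0), with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Clusters were named from 21 fixed marker sets. A name needed at least 3 markers at 50 CPM or more and 2-fold above the median cluster (pseudocount 10 CPM), a mean log2 marker score of at least 2, and no rival lineage above 0.75 of that score. Where another class had more markers among the top 10 genes than the best-scoring class, and at least 3, the cluster was assessed as that other class. With fewer than 3 such markers it stayed unnamed. Names carry the ending "-like" because they rest on transcripts alone. This naming rule was changed after the clusters were seen, from fold over all other cells to fold over the median cluster, because abundant classes masked their own markers. Ranked against all other cells, cluster 14 of the mesenchymal class has 6 tendon cell markers among its top 10 genes. Cluster 6 has 1 fat cell marker there (Cfd) and none of its own. Clusters are therefore also given by number, and values were recomputed without each of these 2 clusters. Mesenchymal-like cells were clustered again at resolution 0.5. Of these subclusters, 5 carries immune genes, 6 keratinocyte genes and 10 muscle genes, and values were recomputed without them.

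UMIs were summed over the cells of each class and library, and a gene's level is its CPM of that sum. Ratios are irradiated over control on the log2 scale, with exact conditional intervals for a pair of Poisson counts at 95%. Shares of cells have exact Clopper-Pearson intervals. Both kinds cover counting error only and say nothing about variation between mice. Cells are not replicates, so no p-values were computed. Ratios were made for the 6 classes with at least 200 cells in each library. The class sums held 60343993 and 17564107 UMIs for mesenchymal-like, 15488378 and 25657468 for macrophage and monocyte-like, 2522581 and 5889602 for neutrophil-like, 53637494 and 38535024 for keratinocyte-like, 9529362 and 5497201 for endothelial-like and 2254719 and 2766840 for dendritic-like cells, control first.

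Of each of 37 gene lists, members with at least 20 UMIs in a class were used. A member counts as higher or lower when its ratio is at least 1.5-fold and its interval leaves out equality. List medians were set beside those of 10000 random lists of the same size, matched in 20 bins of expression, as a description and not a test. Up to 4 members per list are named, those with the largest absolute ratio among members with at least 50 UMIs. Single genes were named by rule from those with at least 100 UMIs and at least 50 CPM in the higher library: the 12 highest and 12 lowest ratios in the mesenchymal class and 8 each way in the others. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed gene models were left out. So were genes whose level lay under 0.25 of their level in another class of the same library, since free RNA can carry them. A fixed set of genes (Cdkn1a, Mdm2, Mki67, Top2a, Sox9, Acan, Runx2, Scx, Tnmd, Col1a1 and Pdgfra) is named in the mesenchymal class whatever their values. Another gene of that set and a list member that the rules would name are not reported here. A few genes outside these rules, such as C1qa, H2-D1, B2m, Krt6b, Krt16 and the leading genes of clusters, were chosen after their values were seen.

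Cells carrying mitosis transcripts were counted after each cell was thinned to 2000 UMIs, as those with at least 2 UMIs over the mitosis list, and shallower cells were left out. Tested on simulated data, made by redrawing the mesenchymal counts of 17207 genes with 200 genes altered, the size rule called 38.8% of genes altered 1.5-fold, 88.7% of those altered 2-fold and 97.2% of those altered 3-fold. It called 0.907% of unaltered genes, and 95.7% of intervals covered the true ratio. The counts were drawn from the Poisson model that the intervals assume, with no variation between cells, mice or libraries. These rates therefore check the calculation and cover counting error only. TMM scaling (edgeR 4.0.16 in R 4.3.3, used for scaling only) moved ratios by 0.30 in neutrophil-like and by 0.10 in macrophage and monocyte-like cells, and by less than 0.02 in the other classes.

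Alternatives tried were a looser cell filter (200 genes, 500 UMIs, 20% mitochondrial) and a stricter one (1000 genes, 2000 UMIs, 5%), doublets kept, resolutions of 0.5 and 2.0, each library clustered by itself, and cells thinned before clustering. For ratios they were TMM and median-of-ratios scaling, the mean over cells, and subclusters with at least 50 cells in each library weighted alike. Lists were also taken with no UMI minimum above 0 and with 100 UMIs, subclusters without cell-cycle genes and with genes centred in each library, and mitosis shares at 1000 and 4000 UMIs and with 1 or 4 UMIs over the list. Added after seeing the data were the equal doublet threshold, keratinocytes left out of the denominator, clustering without the interferon and p53 lists, and the ratios without the mixed subclusters, without cluster 14 and without cluster 6. Figures were drawn with matplotlib 3.10.9.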

Results

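Single-cell transcriptomes were collected from the tendon injury site of male C57BL/6 mice 7 days after a burn of 30% of the body surface with transection of the Achilles tendon, an injury after which cartilage and bone form in soft tissue (traumatic heterotopic ossification). The comparison asks how radiotherapy given after the injury alters the cells at the site, and the fate of mesenchymal cells in particular. The control library came from injured mice without radiation and the irradiated library from injured mice given a single dose of 7 Gy to the site. There were no replicates, and the number of mice behind each library is not given, so each difference describes these 2 libraries and no test was made. The tissue was unsorted. The control library held 11369 barcodes with 180080740 UMIs in total (median 10423 per barcode), and the irradiated library 8302 barcodes with 111753092 UMIs (median 9118). After filtering, 8698 control cells and 7146 irradiated cells were kept. Barcodes above the mitochondrial limit made up 14.9% of the control library and 6.13% of the irradiated one. Intervals below are 95% intervals, exact Poisson or Clopper-Pearson, and cover counting error only. Genes and list members are called higher or lower by a rule of size (at least 1.5-fold, with an interval that leaves out equality), not by a test.

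At the irradiated site the mesenchymal-like share of cells was lower and the shares of macrophage-like, neutrophil-like and T or NK-like cells were higher. Mesenchymal-like cells, the collagen-producing fibroblasts and their relatives from which ectopic cartilage and bone arise, made up 26.6% of control cells (25.7 to 27.6) and 9.12% of irradiated cells (8.47 to 9.82), a share 2.92-fold higher in the control (2.67 to 3.19). Macrophage and monocyte-like cells made up 21.8% of control and 36.4% of irradiated cells (1.67-fold, 1.58 to 1.77). Neutrophil-like cells made up 9.66% and 17.8% (1.84-fold, 1.69 to 2.01). T and NK-like cells made up 1.59% and 3.61% (2.28-fold, 1.84 to 2.82). Shares in a library add up to a whole, so the lower mesenchymal-like share by itself raises the other shares. The higher immune shares are therefore not separate from it, and numbers of cells in the tissue were not measured.

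Keratinocyte-like cells, from the overlying skin, made up 24.2% of control and 17.8% of irradiated cells, so how much skin entered each digest can set every other share. With keratinocyte-like cells left out of the denominator, the mesenchymal-like share was 35.1% in the control and 11.1% in the irradiated library. Endothelial-like cells made up 5.85% and 4.51%, and pericyte and smooth muscle-like cells 3.18% and 2.60%. Schwann-like cells, the glia of peripheral nerve, made up 1.18% and 1.88%. Dendritic-like cells made up 2.98% and 3.61%, and the share was lower rather than higher in the irradiated library under the stricter cell filter. Osteoclast-like cells, which resorb bone, made up 0.977% and 0.980%, and lymphatic endothelial-like cells 0.632% and 0.630%. Clusters left unnamed held 1.31% and 1.02%. The neutrophil-like share depended on depth: its log2 ratio was 0.88 as reported and 1.57 when every cell was thinned to 2000 UMIs and shallower cells were left out.

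**Figure D1:**
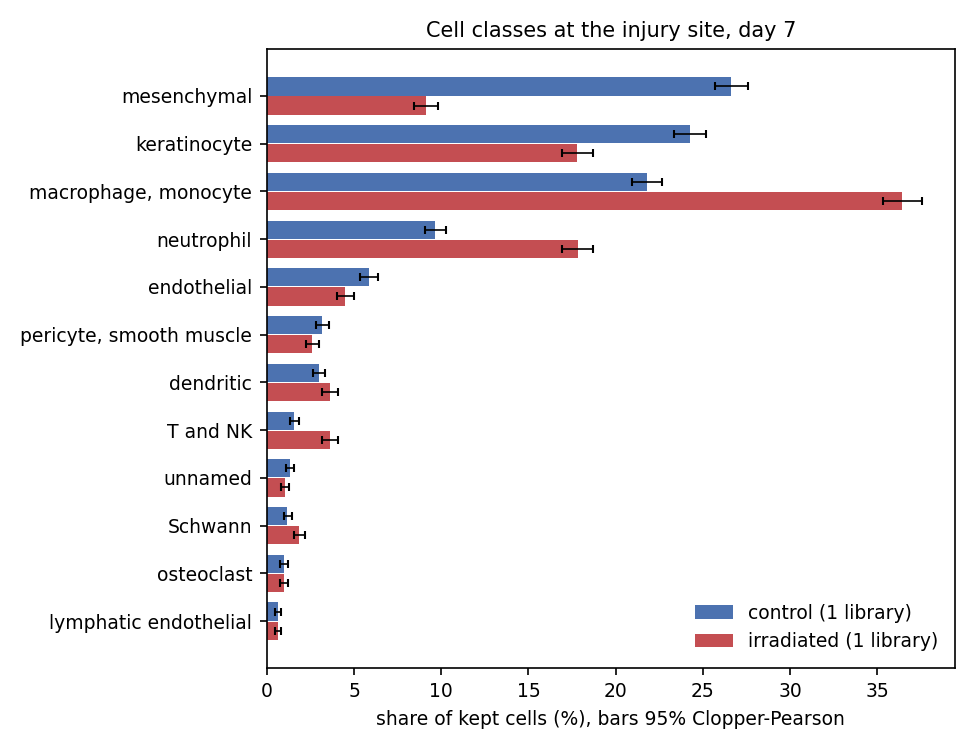
Share of kept cells (%, horizontal axis) in each named class, for the control library (blue, 8698 cells) and the irradiated library (red, 7146 cells); bars start at 0 and error bars are 95% Clopper-Pearson intervals. The mesenchymal bars stand at 26.6% and 9.12%, and the macrophage and monocyte bars at 21.8% and 36.4%.

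Irradiated mesenchymal-like cells had higher levels of interferon-stimulated genes and of p53 target genes than control cells, and lower levels of cartilage, contractile and cell-cycle genes. All 19 measured members of the interferon list were higher, with a median log2 ratio of 3.16, above the medians of all 10000 random lists matched on expression. Irf7, a transcription factor that drives interferon production, stood at 4.26 CPM (UMIs of the gene scaled to the class total) in the control and 93.8 in the irradiated library (log2 ratio 4.46, 4.27 to 4.66). Rsad2, an antiviral enzyme, stood at 2.35 and 51.0 CPM, Ifit1, which binds foreign RNA, at 7.34 and 113 CPM, and Oas1a at 0.862 and 13.5 CPM. With subclusters weighted alike in both libraries the median was 2.54.

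Of 23 p53 targets, 14 were higher and none lower (median 0.87, above all matched random lists). Cdkn1a (ENSMUSG00000023067; GRCm38 chromosome 17, bases 29090976 to 29100727), the cell-cycle inhibitor p21, stood at 36.0 CPM in the control and 348 CPM in the irradiated library, 9.66-fold higher. The others with the widest ratios were Gdf15, a stress-induced cytokine (log2 ratio 3.30), Eda2r (2.89) and Trp53inp1 (2.25). Gdf15 had 177 irradiated UMIs in immune-gene subcluster 5, 82 in subcluster 0, and 1, 4, 7 and 6 in subclusters 1 to 4. In subclusters 1 to 4 its intervals included equality. Mdm2, the ubiquitin ligase that restrains p53, stood at 45.8 and 99.3 CPM (1.12, 1.03 to 1.20). Bax, which permeabilises mitochondria, was among the 14. In each of the 4 largest mesenchymal clusters the p53 median was positive: 0.78 in cluster 4, 0.91 in cluster 5, 0.88 in cluster 6 and 1.16 in cluster 14. Within subclusters 0 to 4 it was 1.00, 0.81, 1.08, 0.72 and 0.13. The list of cell death regulators had a median of -0.01, with Bcl2 and Birc3, both survival genes, higher. Bcl2 also leads subcluster 8 (Gpc5, Slc26a7), which held 1.12% of control and 4.91% of irradiated mesenchymal-like cells, so its class ratio moves with that share.

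Cartilage genes were lower. Of 19 measured members of the chondrogenic list, 9 were lower and 2 higher (median -0.80, below all matched random lists). Col2a1 (ENSMUSG00000022483; GRCm38 chromosome 15, bases 97975602 to 98004695), the main collagen of cartilage, had 1108 UMIs in the control and 30 in the irradiated library, or 18.4 and 1.71 CPM (log2 ratio -3.43, -4.00 to -2.90). Cnmd, a cartilage glycoprotein that restrains vessel growth, stood at -3.24, Col9a2 at -3.00 and Col9a1, another chain of the same cartilage collagen, at -2.54. The 2 higher members were Prg4, the joint lubricant lubricin, and Chad. Earlier or broader genes of the lineage lay within the size rule: Sox9 (ENSMUSG00000000567), the master regulator of cartilage, stood at 139 and 106 CPM (-0.39, -0.47 to -0.32) and Acan, the main cartilage proteoglycan, at 333 and 244 CPM (-0.45). Acan was not lower with subclusters weighted alike (0.26). Without cluster 14, which carries tendon genes, the chondrogenic median was -1.28, and without cluster 6 it was -0.44.

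Bone genes gave no common direction. Of 14 measured members of the osteogenic list, 1 was higher and 2 lower (median -0.14, percentile 17.6 among matched random lists), and the median was 0.10 with subclusters weighted alike. Runx2 (ENSMUSG00000039153; GRCm38 chromosome 17, bases 44495987 to 44814797), the transcription factor required for bone formation, stood at 157 CPM in the control and 91.5 CPM in the irradiated library (-0.78, -0.86 to -0.71). Ibsp, bone sialoprotein, stood at -1.18 on low counts, Phex at 0.80 and Postn, periostin, at -0.58. Col1a1 was close in both libraries, 19622 and 21499 CPM (0.13), as was Pdgfra, a receptor of fibroblast precursors (149 and 176 CPM, 0.24).

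Tendon genes were higher as a list: 8 of 19 were higher and 1 lower (median 0.49, above all matched random lists), led by Chodl (2.86), Cilp2 (1.67), Angptl7 (1.53) and Tppp3, a marker of the tendon sheath (1.38). Chodl also leads subcluster 10, which carries muscle genes and held 0.346% of control and 1.84% of irradiated mesenchymal-like cells. Its class ratio moves with that share. Scx, the transcription factor of tendon progenitors, stood at 100.3 and 141 CPM (0.49) and Tnmd, tenomodulin, at 188 and 188 CPM (-0.00). Cluster 14, which carries tendon genes, held 4.70% of control and 1.64% of irradiated cells. Without cluster 14 the tendon median was 0.10 and the ratio of Scx -0.12, and within subclusters 0 to 4 the tendon medians were 0.36, -0.30, 0.21, 0.29 and 0.66. Contractile genes were lower, 7 of 14 with none higher (median -0.59): Acta2, smooth muscle actin of myofibroblasts, stood at 949 and 436 CPM (-1.12), Myl9 at -1.15 and Actg2 at -1.15. Acta2 and Actg2 also lead subcluster 2, which held 20.1% of control and 9.82% of irradiated mesenchymal-like cells. Their class ratios move with that share.

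Genes of the fibroblast progenitor list were higher, 14 of 17 with none lower (median 1.32). Clec3b stood at 52.7 and 336 CPM, Dpp4, which marks an early fascial progenitor, at 2.98 and 18.2, Ly6c1 at 92.9 and 544, and Smpd3 at 0.298 and 3.07. Clec3b and Pi16 of this list also lead cluster 6, whose share of the mesenchymal-like cells differed (18.4% and 51.7%), and without that cluster the list median was 0.43. Within subclusters 0 to 4 it was 1.00, -0.13, 0.58, 0.36 and 0.74. Fat cell genes were higher in 9 of 13, including Adipoq (3.32) and Cidec (4.08), but the list median was -0.11 with subclusters weighted alike and -0.24 without cluster 6.

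Antigen presentation genes were higher in 15 of 16 (median 1.78), with H2-D1, a class I chain, at 99.5 and 575 CPM and its partner B2m at 244 and 1094 CPM. Complement genes were higher in 15 of 16 (median 1.55), among them C4b (2.17), Cfb (1.98) and C3ar1 (2.48), and inflammatory mediators in 16 of 20 (median 1.25), led by the chemokines Ccl5 (5.79), Ccl4 (3.26), Ccl3 (2.87) and Cxcl3 (2.71). Lists of genes belonging to blood and immune cells were also higher in this class, and those genes can enter a droplet as free RNA. The red cell list had a median of 2.94, the neutrophil transcript list 1.65 and the inflammatory macrophage list 2.28, and C1qa, made by macrophages, stood at 9.64 and 39.6 CPM. With subclusters weighted alike the medians were 0.61 for complement, 1.03 for antigen presentation and 0.96 for inflammatory genes. Secreted factors of senescent cells were higher in 13 of 20 (median 0.79), with Gdf15 (3.30), Ccl8 (2.60), Mmp3, stromelysin (1.77), and Cxcl2 (1.55). The Gdf15 ratio has the limit given above, with 10.3 and 116 CPM in immune-gene subcluster 5. Ccl8 also leads macrophage-like cluster 1, and its source here was not tested.

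The 12 genes with the highest ratios in the class were Cfd, Ifi27l2a, Irf7, Ifit1, Ifit3, Cdkn1a, Ifi205, Bst2, Car3, Ifi203, Tnxb and Cxcl10. Ifi205 and Tnxb also lead subcluster 0, which held 17.4% of control and 43.4% of irradiated mesenchymal-like cells, so their class ratios move with that share. Cfd, the complement protease adipsin, stood at 4.08 and 313 CPM (6.26) and Car3, a carbonic anhydrase abundant in fat, at 9.16 and 81.6 CPM (3.15). Both lead a small subcluster that also carries immune genes. Both ratios turned negative without the subclusters that carry genes of other cell types, and without cluster 6. Bst2, tetherin, stood at 61.5 and 548 CPM, Ifi27l2a at 19.4 and 510, and the chemokine Cxcl10 at 26.0 and 180. Within subclusters 0 to 4 the log2 ratio of Cxcl10 was 2.95, -0.30, 1.04, 1.53 and 0.93. The 12 with the lowest ratios were Pdzrn4 (-2.46), Mest (-2.21), Ptn (-2.02), Brinp1 (-1.98), H19 (-1.83), Mdk (-1.50), Brinp3 (-1.44), Capn6 (-1.34), Slc1a3 (-1.31), Epha3 (-1.28), Col24a1 (-1.25) and Cdh2 (-1.20). Mest and H19 are imprinted genes of growing tissue, and stood at 513 and 111 CPM and at 621 and 174 CPM. Ptn and Mdk, pleiotrophin and midkine, are related heparin-binding growth factors, and stood at 763 and 188 CPM and at 230 and 81.0 CPM. Cdh2 is N-cadherin, an adhesion molecule of condensing mesenchyme. Pdzrn4, Brinp1, H19 and Slc1a3 also lead cluster 5 and Brinp3 leads cluster 4, so their class ratios move with the shares of those clusters.

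**Figure D2:**
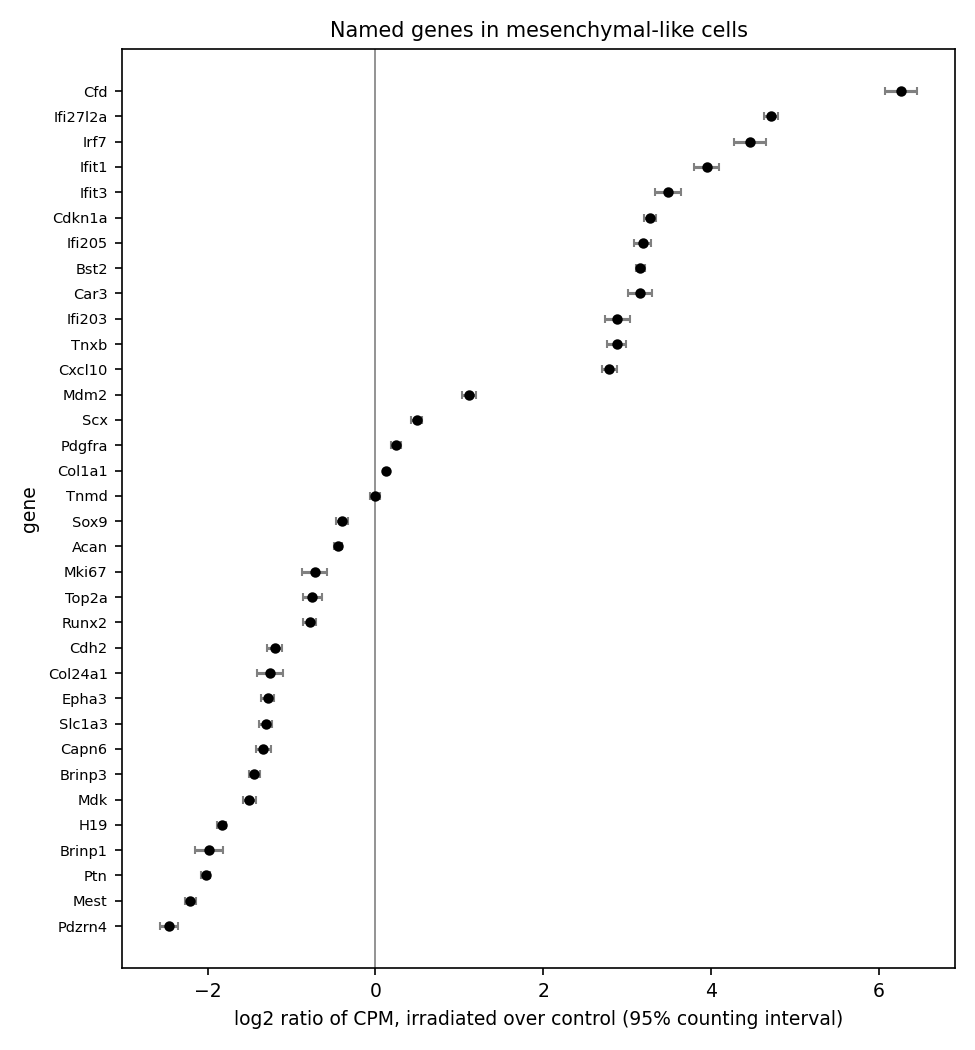
Log2 ratio of CPM in mesenchymal-like cells, irradiated over control (horizontal axis), for the 24 genes with the highest and lowest ratios and the reported genes fixed in advance (vertical axis); points are ratios of summed UMIs of 1 library each and bars are 95% counting intervals. Cdkn1a lies at 3.27, Runx2 at -0.78 and Pdzrn4 at -2.46; Cfd, at 6.26, turns negative when cluster 6 is left out.

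Wnt genes were higher in 9 of 19 and lower in 3 (median 0.53), with the ligand Wnt2 (2.46) and the antagonists Sfrp4 (2.17) and Wif1 (2.09), and the median was 0.10 with subclusters weighted alike and negative within each of subclusters 0 to 4 (-0.55 to -0.01). BMP genes were higher in 7 of 23 and lower in 2 (median 0.25), among them the ligands Bmp7 (1.56), Bmp4 (1.43) and Bmp2 (1.12), which drive bone and cartilage formation, but the median was -0.13 with subclusters weighted alike, and -0.11, 0.06, -0.10, 0.14 and 0.18 within subclusters 0 to 4. TGF-beta genes had a median of 0.13 and hedgehog genes -0.04. Collagens other than those of cartilage had a median of 0.18, with Col15a1 (1.32) and Col18a1 (1.06) of the basement membrane zone higher. Matrix glycoproteins had a median of 0.06 (Prelp 1.67, elastin 1.39, Fbln5 -0.82) and matrix enzymes 0.22 (Mmp3 1.77, Adamts5 1.61, Mmp9 -1.04).

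Fewer irradiated than control cells carried mitosis transcripts in most classes. The share with at least 2 UMIs over 20 mitosis genes, after thinning to 2000 UMIs, was 16.6% of control mesenchymal-like cells (15.1 to 18.2) and 6.77% of irradiated ones (4.94 to 9.01). It was 27.2% and 16.2% in keratinocyte-like cells, 13.2% and 5.77% in endothelial-like cells, and 15.8% and 6.01% in pericyte and smooth muscle-like cells. T and NK-like cells gave 19.0% and 19.6%, with wide intervals. Macrophage-like cells gave 3.84% and 2.30%, dendritic-like 10.4% and 6.88%, Schwann-like 15.7% and 8.06%, and neutrophil-like cells, which do not divide once mature, 3.64% and 1.08%. The interval of the log2 ratio included equality in dendritic-like (-1.56 to 0.35) and Schwann-like cells (-2.26 to 0.27). Shallower cells were left out, 49 control and 17 irradiated in the mesenchymal class, and 373 and 166 in the neutrophil class. Without thinning the mesenchymal shares were 51.1% and 32.1%, and the neutrophil shares 5.83% and 5.34%. How much free RNA adds to these shares is open.

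In the mesenchymal class, 9 of 20 mitosis genes were lower and none higher (median -0.53), with Mki67 at 41.3 and 25.1 CPM (-0.72), Top2a at 76.6 and 45.5 CPM (-0.75) and Kif11, a spindle motor, at -0.96. DNA synthesis genes were lower in 9 of 20 (median -0.51), among them the replication helicase subunits Mcm2 (-0.93) and Mcm3 (-1.03), and DNA repair genes in 8 of 20 (median -0.43), among them Brca2 (-1.27). With subclusters weighted alike, which left out the dividing subcluster, the mitosis median was 0.02, and within subclusters 0 to 4 it was 0.15, -0.57, -0.55, -0.24 and 0.33. The dividing subcluster held 11.4% of control and 4.14% of irradiated mesenchymal-like cells. The DNA synthesis and DNA repair medians given here are over the whole class and can move with that share.

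Clustered again by themselves, mesenchymal-like cells fell into 11 subclusters whose shares differed. Subcluster 0 (Clec3b, Pi16, Sfrp4) held 17.4% of control (15.8 to 19.0) and 43.4% of irradiated mesenchymal-like cells (39.6 to 47.3). Subcluster 1 (Pdzrn4, Slpi, Wfdc3) held 28.1% (26.3 to 30.0) and 4.14% (2.75 to 5.97). Subcluster 2 (Clstn2, Acta2, Tagln) held 20.1% and 9.82%, and subcluster 4 (Ube2c, Top2a), of dividing cells, 11.4% and 4.14%. Subcluster 3, led by the tendon genes Kera, Tnmd and Fmod, held 14.4% and close to that share of irradiated cells (0.906-fold, 0.706 to 1.15).

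The leading genes of these subclusters differ in level between the libraries as well, so a share can reflect a shift in those genes. Clustered without the cell-cycle lists, the log2 ratio for subcluster 2 was -3.06 instead of -1.03. Clustered without the interferon and p53 lists, the log2 ratio for subcluster 0 was 0.55 instead of 1.32; with genes centred within each library, that for subcluster 1 was -1.64 instead of -2.76. Cdkn1a was higher in the irradiated cells of each of the 5 largest subclusters, at 41.5 and 394 CPM in subcluster 0, 27.6 and 254 in subcluster 1, 34.2 and 376 in subcluster 2, 27.0 and 306 in subcluster 3, and 27.4 and 95.5 in subcluster 4. Runx2 stood at -1.25 in subcluster 0, -0.61 in subcluster 2, -0.05 in subcluster 3, -1.20 in subcluster 4 and 0.18 in subcluster 1. The chondrogenic list had a median of -0.83 in subcluster 0, -0.80 in subcluster 1 and -0.76 in subcluster 3, but -0.04 in subcluster 2, where 5 members were higher and 3 lower and Acan stood at 2.26. Col2a1 was found mostly in subclusters 1 and 3 of the control, with 293 and 717 UMIs, against 3 and 5 UMIs in the same irradiated subclusters (log2 ratios -2.82, -5.11 to -1.26, and -5.60, -7.23 to -4.38). Median UMIs per cell were 1.66, 1.46, 1.37 and 1.42-fold higher in the irradiated cells of subclusters 1 to 4, and 1.02-fold higher in subcluster 0.

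**Figure D3:**
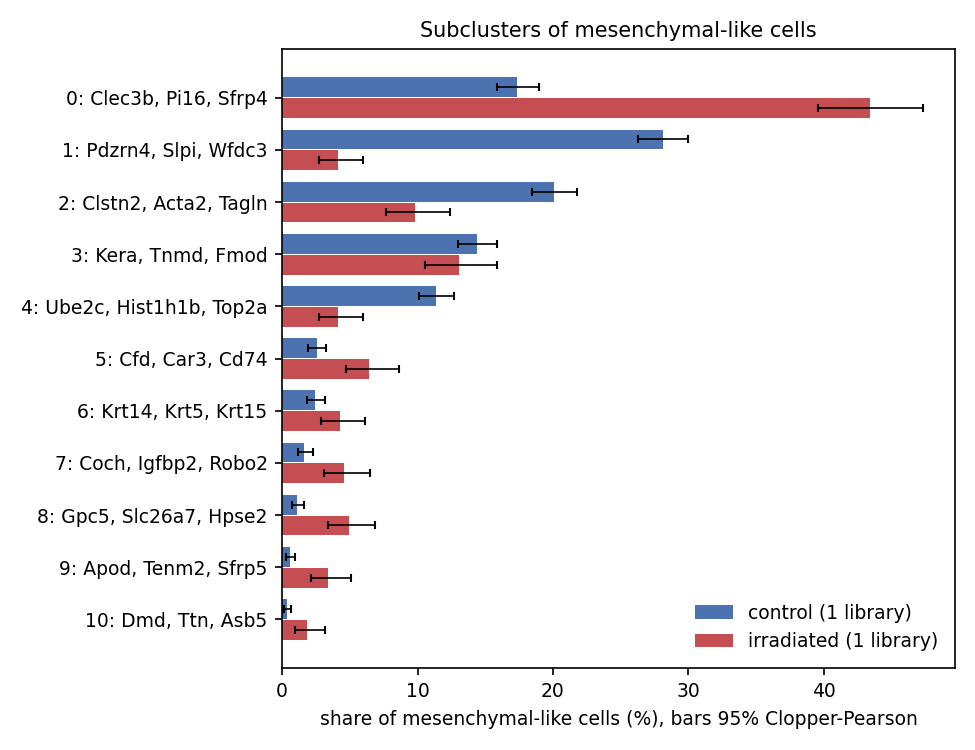
Share of mesenchymal-like cells (%, horizontal axis) in each of 11 subclusters, labelled by number and leading genes, in the control library (blue, 2315 cells) and the irradiated library (red, 652 cells); error bars are 95% Clopper-Pearson intervals. Subcluster 0 stands at 17.4% and 43.4% and subcluster 1 at 28.1% and 4.14%.

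Irradiated macrophage and monocyte-like cells had higher levels of interferon, inflammatory and class I genes and lower levels of several genes of resident and lipid-handling macrophages. The median gene of this class had a log2 ratio of -0.11, and TMM scaling moved all ratios by 0.10, so ratios are best read against that shift. All 19 interferon genes were higher (median 1.66), with Irf7 at 69.1 and 335 CPM (2.28), Isg15, a ubiquitin-like antiviral protein, at 121 and 571 CPM (2.24), and Ifi44 at 2.43. Of the inflammatory macrophage list, 16 of 18 were higher and none lower (median 1.36): Nos2, the inducible nitric oxide synthase, stood at 18.4 and 120 CPM (2.70, 2.53 to 2.88), Ccl5 at 2.39, Ly6c2, a marker of recruited monocytes, at 2.30, and Cxcl10 at 1.92. Inflammatory mediators were higher in 15 of 20 (median 1.26), with Il1a at 2.25 and Cxcl3 at 364 and 1474 CPM. In the same cells the neutrophil transcript list, which can enter as free RNA, was higher in 4 of 4 (median 1.40) and the red cell list had a median of 1.02, and irradiated neutrophil-like cells held Cxcl3 at 3011 CPM. Antigen presentation genes were higher in 9 of 16 (median 0.67), led by H2-Q7 (2.88) and H2-Q4 (1.82).

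The resident and repair list had 4 members higher and 7 lower (median -0.17). Arg1, arginase of wound macrophages, stood at 242 and 934 CPM (1.95), whereas Igf1, a growth factor, stood at 167 and 39.8 CPM (-2.07), Retnla at -1.99 and Fabp5 at -1.90. Fabp5 is abundant in keratinocytes, where it also stood lower (17761 and 7050 CPM). Of the lysosome and lipid genes, 6 of 20 were lower (median -0.22), with Fabp4 (-2.47), Lpl, lipoprotein lipase (-1.84), and Gpnmb (-1.42). The genes with the highest ratios were Ly6a (3.10), Ifi205, H2-Q7, Nos2, Ereg, Inhba, Saa3 and Cfb (2.32). Ereg is an epidermal growth factor ligand, Inhba an activin subunit at 33.8 and 177 CPM, and Saa3 an acute-phase protein. Those with the lowest were Slc40a1, the iron exporter ferroportin (57.5 and 15.9 CPM), Lpl, Vcam1, Npl, Clec10a, a lectin of alternatively activated macrophages, Gas6, Gpnmb and Wwp1 (-1.40). Glycolysis and hypoxia genes were higher in 6 of 20 (median 0.35), and 7 of 22 p53 targets were higher (median 0.40; Phlda3 1.68, Cdkn1a 413 and 691 CPM). Collagen transcripts had a median of -2.02 in these cells, with Col1a1 at 145 and 32.3 CPM. They can enter as free RNA: mesenchymal-like cells held Col1a1 at 19622 and 21499 CPM and made up 26.6% and 9.12% of cells. A change within macrophage and monocyte-like cells was not told apart from that.

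Cluster 0 (class II genes) was the largest of the class in both libraries, with 41.3% of control and 39.5% of irradiated macrophage and monocyte-like cells. Cluster 1 (Mrc1, Folr2, C1q genes) held 36.8% and 14.0%, and cluster 9 (Arg1, Mmp12, Nos2) 7.39% and 20.2%. Cluster 11 (Ly6c2, Plac8) held 2.74% and 19.4%. Mrc1, Arg1, Nos2, Ly6c2 and the interferon genes that lead clusters 1, 9 and 11 differed in level between the libraries, so these shares say where the cells lie and are not separate results. Cluster 19 (Chil3, Ccr2) held 11.7% and 6.88%. Within clusters 0, 1, 9 and 19 the interferon medians were 1.12, 1.40, 2.01 and 1.09, and within cluster 11 it was -0.23. The inflammatory medians were 0.49, 0.81, 0.82 and 0.55 within clusters 0, 1, 9 and 11, and the highest was within cluster 19.

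Irradiated neutrophil-like cells had higher levels of interferon and inflammatory genes. The median gene of this class stood at -0.31 and TMM scaling moved all ratios by 0.30, so a ratio of -0.31 marks the middle of the class. All 18 measured interferon genes were higher (median 1.99), with Ifit3 at 26.2 and 230 CPM (3.14, 2.78 to 3.52), Usp18, which dampens interferon signalling, at 3.11, Ifit1 at 3.06 and Rsad2 at 131 and 917 CPM (2.81). Inflammatory mediators were higher in 13 of 20 and lower in 3 (median 0.92): Cxcl3 stood at 881 and 3011 CPM, Il1a at 337 and 1078, and Nos2 at 1.73, whereas Il6 stood at 40.4 and 5.43 CPM (-2.90). Within clusters 2, 10 and 15 of this class the interferon medians were 1.86, 0.70 and 1.39, and the inflammatory medians 0.93, 0.04 and 0.35.

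The maturation and activation list was split, 5 higher and 6 lower of 20 (median -0.08). Camp, the cathelicidin of secondary granules, stood at 204 and 5.77 CPM (-5.14), Ngp at 145 and 17.0 (-3.09) and Ltf, lactoferrin, at 84.4 and 17.1 (-2.30), whereas the chemokine Ccl3 stood at 2569 and 7136 CPM (1.47). With each cell weighing the same, the ratios of Camp, Ngp and Ltf were -2.74, -0.90 and -0.48. The other genes with the highest ratios were Oasl1, Cmpk2, Ifit3b and Ifi47, all induced by interferon, and the other lowest were Mmp12 (-3.60), Pip5k1b, Camk1d, Fry and Eprs (-1.22). Glycolysis genes were higher in 5 of 18 (median 0.30), among them Hk2, hexokinase (1.33), and Ldha (0.80). None of 18 measured p53 targets was higher and 2 were lower, Trp53inp1 (-0.62) and Btg2 (-0.71), with a list median of -0.03 against -0.25 for matched random lists. Read against the class median of -0.31, neither member is lower by the size rule. Collagen genes, which can enter as free RNA from mesenchymal-like cells, had a median of -2.16 in these cells. Cluster 2 (Retnlg, Cxcr2) held 26.5% of control and 56.7% of irradiated neutrophil-like cells, cluster 10 (Il1r2, Csf3r) 58.5% and 12.9%, and cluster 15 (Ccl3, Ccl4, Cxcl2) was 2.03-fold higher in its share (1.65 to 2.50). Leading genes of these clusters differed in level too (Ccl3, for example), so the shares are not separate results. Median UMIs per neutrophil-like cell were 2109 and 3154.

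Irradiated keratinocyte-like cells had higher interferon and p53 target genes and, over the class as a whole, lower glycolysis and hypoxia genes. All 19 interferon genes were higher (median 2.73), though from low levels: Isg15 stood at 4.40 and 52.0 CPM (3.56) and Ifit1 at 0.541 and 9.78 (4.18). Transcripts of other cell types were higher in the same cells, with a median of 1.90 for the red cell list and 1.31 for the inflammatory macrophage list, and Ifit1 stood at 417 CPM in irradiated neutrophil-like cells. Of 23 p53 targets, 16 were higher and none lower (median 0.95), with Ddit4l (2.95), Eda2r (2.32) and Trp53inp1 (1.97). Class I and proteasome genes of antigen presentation were higher, 13 of 16 on that list (median 1.16), B2m standing at 160 and 599 CPM. Of the keratins induced in wounded epidermis, Krt6b stood at 2294 and 843 CPM (-1.45) and Krt16 at 4357 and 1974 CPM (-1.14). Cluster 3, which these keratins lead, held 32.4% of control and 14.1% of irradiated keratinocyte-like cells, a share that moves with those keratins.

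Also lowest in keratinocyte-like cells were Car2 (-2.42), Csta1 (-1.69), Sprr2h, Flg, filaggrin of the cornified layer (333 and 132 CPM), Fabp5 and Casp14, a protease of cornification (-1.07). The highest were Mgmt, which repairs alkylated DNA (13.1 and 70.1 CPM, 2.42), Trp53inp1, Ccnd2, a cyclin (70.9 and 230 CPM), Cxcl14, Rev1, a polymerase that bypasses DNA damage (1.53), Col23a1, Ccng1 and Fbxw9 (1.39). Csta1 and Fabp5 also lead cluster 3 and Cxcl14 leads cluster 12, so their class ratios move with the shares of those clusters. Glycolysis and hypoxia genes were lower in 8 of 20 with none higher (median -0.44), with Adm (-1.33), Bnip3 (-1.10) and the glucose transporter Slc2a1 (218 and 105 CPM, -1.05). This list was taken over the class only, so its median can move with the share of cluster 3. Genes of the senescence list were lower in 10 of 20 and higher in 2 (median -0.68): Mmp10 stood at -2.27, Mmp13 at -1.73 and Timp1 at -1.63, against 2.07 for Cxcl2. The collagen list, whose transcripts can enter as free RNA from mesenchymal-like cells, had a median of -1.04 in these cells. Mmp13 also leads mesenchymal cluster 14 and can enter the same way. Clusters 8 (Col17a1) and 12 (Lhx2, Lgr5, genes of the hair follicle) held 15.5% and 12.1% of control and 27.3% and 22.2% of irradiated keratinocyte-like cells.

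Irradiated endothelial-like cells had higher p53 target, interferon and inflammatory genes. Of 23 p53 targets, 18 were higher and none lower (median 1.20, above all matched random lists): Cdkn1a stood at 108 and 570 CPM, Gdf15 at 8.92 and 76.9 (3.11), Eda2r at 34.2 and 147 (2.10) and Ccng1 at 17.5 and 71.1 (2.02). All 19 interferon genes were higher (median 1.72), with Irf7 at 15.2 and 131 CPM (3.10) and Ifit2 at 2.90. Inflammatory mediators were higher in 13 of 20 (median 1.27) and antigen presentation genes in 12 of 15 (median 1.02), beside a median of 2.32 for neutrophil transcripts and 1.28 for red cell transcripts in the same cells. Early response genes were higher in 7 of 20 (median 0.51), with Egr1 at 274 and 593 CPM. Vessel growth genes were higher in 3 of 19 and lower in 1 (median 0.25): Vegfa stood at 1.07 and Aplnr, the apelin receptor of sprouting vessels, at 438 and 271 CPM (-0.69). Bmp6, an endothelial regulator of iron balance, stood at 1.92 and Bmp2 at -1.24.

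The genes with the highest ratios in endothelial-like cells were Timp4 (4.06), Ephx1 (3.57), Gdf15, Irf7, Gas6 (28.3 and 239 CPM), Lpl, Ifit2 and Ifit3. The lowest were Glycam1, a ligand for lymphocyte homing (52.6 and 13.5 CPM, -1.97), Flrt2, Serpinb1a, Nox4, Fam155a, Piezo2, a mechanically gated channel, Mest (471 and 214 CPM) and Shroom2 (-1.08). With each cell weighing the same, Nox4 stood at -2.37, Fam155a at -2.13 and Piezo2 at -2.06. Cluster 26 (Timp4, Gpihbp1, Cd36), of capillary cells, held 3.93% of control and 25.5% of irradiated endothelial-like cells, and cluster 7 (Selp, Plvap) 96.1% and 74.5%, so Timp4 moves with that share. Within cluster 7 the p53 median was 1.22 and the interferon median 1.70.

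**Figure D4:**
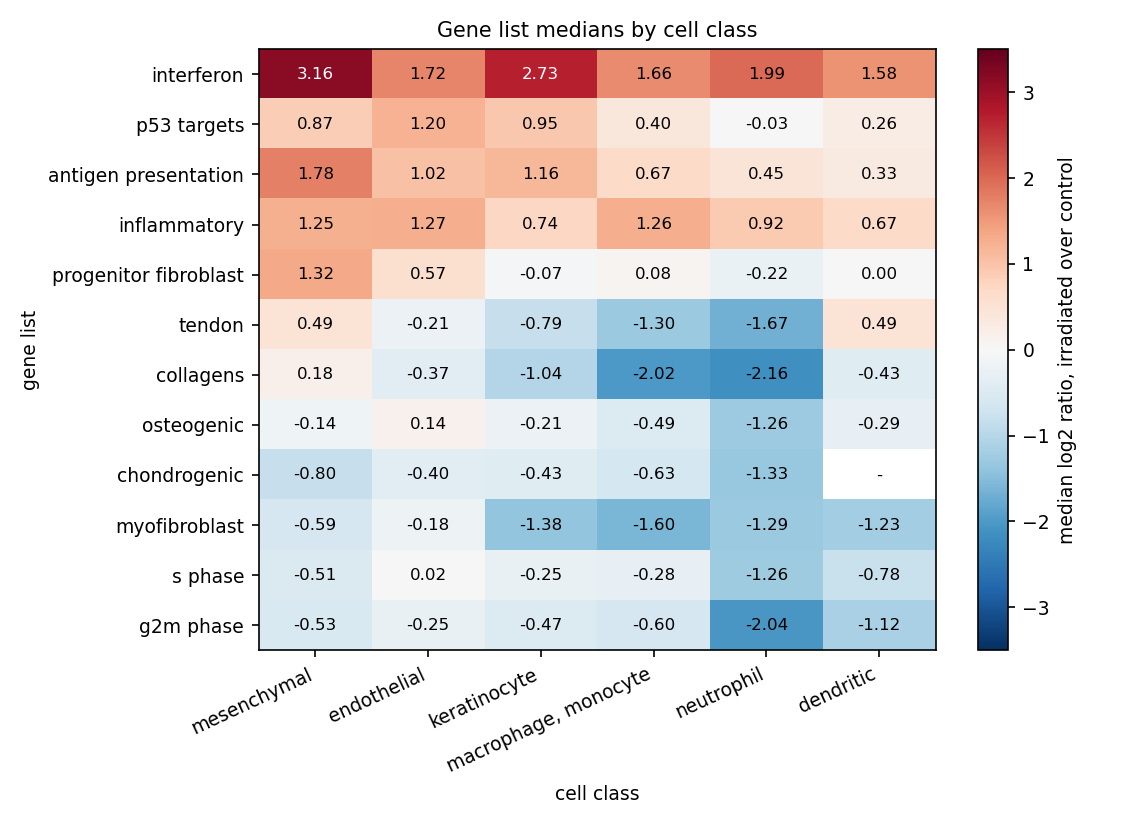
Median log2 ratio (irradiated over control, colour and printed value) of 12 gene lists (vertical axis) in 6 cell classes (horizontal axis), each from 1 library per group; red is higher and blue lower in the irradiated library, and a dash marks a list with too few measured genes. The interferon list is positive in all 6 classes, from 1.58 to 3.16, and the p53 list runs from -0.03 in neutrophil-like to 1.20 in endothelial-like cells; neutrophil values are read against a class median of -0.31.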

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

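No test in this part was chosen after the result was seen; each result is listed because a gene list had opposite directions in different cell classes, and the difference between classes was not tested. The list of resident and repair macrophage genes had a median log2 ratio of 1.05 in mesenchymal-like cells and -1.37 in dendritic-like cells, a difference of 2.42, though it was -0.52 to -0.03 within mesenchymal subclusters 0 to 4, beside a share of immune-gene subcluster 5 of 2.55% and 6.44% and a share of monocyte RNA in mesenchymal-like cells (cluster 11 as the source) of at most 0.920% in the control and 2.69% in the irradiated library. The senescence list of secreted factors had a median of 0.79 in mesenchymal-like cells and -0.68 in keratinocyte-like cells, a difference of 1.47. Neither median was separated from transcripts of other cell types. Mmp13, lower in keratinocyte-like cells, leads mesenchymal cluster 14, and the collagen list stood at -1.04 in keratinocyte-like cells. Among the higher mesenchymal members, Ccl8 leads macrophage-like cluster 1, and Gdf15 stood at 10.3 and 116 CPM in immune-gene subcluster 5.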

How the results depend on the processing

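The alternatives chosen only after the data were seen were the equal doublet threshold, keratinocytes left out, clustering without the interferon and p53 lists, and leaving out the mixed subclusters, cluster 14 or cluster 6. No paired analysis was possible because there is 1 library per group. Of 103 alternative values for class shares, 97 stayed within the counting interval and none of the called differences reversed; for the mesenchymal-like share all 10 did so. Of 35 values for mitosis shares 33 stayed, of 32 for subcluster shares 26, of 1135 for list medians 835 and of 509 for named genes 296, with 4 list values and 5 gene values reversed. Reversed means a change of sign where the reported value was past 1.5-fold. Counting results of any size, 82 list values and 14 gene values changed sign. So did 7 values for class shares, 1 for mitosis shares and 1 for subcluster shares. The macrophage-like share had a log2 ratio of 0.74, and 0.62 with keratinocytes left out, and the neutrophil-like share 0.88, against 1.20 under the stricter filter and 1.57 in thinned cells. For subcluster 0 the ratio was 1.32, against 0.55 without the interferon and p53 lists and 0.82 with centring; for subcluster 1 it was -2.76 and with centring -1.64; for subcluster 4 it was -1.46 and without the interferon and p53 lists -0.88. With the mean over cells the mesenchymal medians were 3.05 for interferon, -0.94 for mitosis, -1.07 for cartilage and 0.40 for tendon genes, the macrophage interferon median 1.57, and the interquartile range of mesenchymal ratios 0.68 instead of 0.56. With subclusters weighted alike, which leaves out the dividing subcluster and all but subclusters 0, 2 and 3, the medians were 2.54 for interferon, 0.016 for mitosis, 0.10 for bone, 0.25 for tendon and -0.11 for fat cell genes, and Car3 stood at -0.049. The stricter filter gave 0.70 for p53 targets and 0.55 for tendon genes, and no UMI minimum gave 0.13 for bone genes. Without the mixed subclusters the medians were -0.43 for mitosis and -0.85 for cartilage genes, and the ratio of Cfd, mesenchymal (log2), was -3.95 and that of Car3, mesenchymal (log2), -2.28. Without cluster 14 they were -0.44 for mitosis, -1.28 for cartilage and 0.10 for tendon genes. Without cluster 6 they were -0.31 for mitosis, -0.44 for cartilage, 0.61 for tendon and -0.24 for fat cell genes, with Cfd at -5.67 and Car3 at -4.48. The neurotrophic median in macrophage-like cells, 0.60 on 4 genes, was -0.087 with the mean over cells and -0.73 with no minimum. Beyond what each alternative leaves out, the cause was not tested. Recovery of 2-fold differences, simulated with counting error only, was 75.8% in neutrophil-like cells, 83.9% in dendritic-like cells and 88.7% in mesenchymal-like cells. The irradiated mesenchymal class rests on 652 cells.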

Other observations

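The tests of the share of the tendon-gene cluster, of the depth of other classes and of doublets with other cell types were chosen only after the results were seen. Dendritic-like cells, 259 in the control and 258 in the irradiated library, had higher interferon and inflammatory genes and lower genes shared with repair macrophages. Of 19 interferon genes 18 were higher (median log2 ratio 1.58), with Cxcl10 at 22.2 and 157 CPM (2.82), Isg15 at 150 and 502 CPM and Ifit3 at 1.78. Saa3, an acute-phase protein, stood at 4.88 and 285 CPM (5.87, 5.02 to 6.88) and Ly6c2, a marker of monocytes, at 2.27. The other highest genes were Ccdc138 (2.03), Spib, a transcription factor of plasmacytoid dendritic and B cells (1.93), Cd69, an early activation marker (1.83), and Fgf13 (1.82). Saa3, Ly6c2 and Spib also lead cluster 31 of this class (Siglech, Ccr9), which held 17 control and 26 irradiated cells. Their class ratios move with its share. Gpnmb had 165 UMIs in the control and 4 in the irradiated library (-5.66, -7.55 to -4.28), and Trem2, a lipid receptor of macrophages, stood at -2.71. The other lowest were the heat shock genes Hspa1b (-2.01) and Hspa1a (-1.81), Ank2, Gab1, Mgl2, a lectin (-1.23), Il12b, a subunit of interleukin 12 and 23 (-1.20), and Adam23. Mitosis genes were lower in 8 of 12 (median -1.12). Red cell transcripts, which can enter as free RNA, had a median of 7.35 in the same cells, and their source was not tested.

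The interferon and p53 lists parted by cell type, though the differences were not tested. In pericyte-like cluster 18 the medians were 2.64 for interferon and 0.55 for p53 targets, in Schwann-like cluster 22 they were 1.95 and 0.69, and in osteoclast-like cluster 24 they were 1.60 and 0.46. In T cell-like cluster 21 they were 2.33 and -0.02. Among macrophage and monocyte-like clusters the p53 median was 1.07 in cluster 1, which carries Mrc1 and Folr2 of resident macrophages, and 0.05 to 0.55 in clusters 0, 9, 11 and 19. In neutrophil-like clusters 2, 10 and 15 it ran from -0.24 to 0.04.

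Interferon genes were higher in the irradiated cells of all 6 classes compared. Monocyte RNA in mesenchymal-like droplets was argued against: set from Lyz2, Tyrobp, Ctss and Fcer1g, it made up at most 2.69% of irradiated mesenchymal RNA, and the observed excess of the list was 8.70 times what that share would bring (median over 19 genes), though no other class was tested. A shift of cells between clusters was argued against too, since the median over 24 single clusters was 1.98, with 22 of them at 1 or more and only monocyte-like cluster 11 below 0 (-0.23). The radiation itself stays open as an untested biological explanation. Library and treatment coincide, so a difference between mice or in handling stays open.

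Cartilage genes were lower in irradiated mesenchymal-like cells. A smaller share of the subclusters that carry them was argued against as the whole cause by the whole list. Its median log2 ratio was -0.80 over all cells and -0.79 with subclusters 0, 2 and 3 weighted alike, which leaves out subcluster 1. Within subcluster 3 the list median was -0.76 and within subcluster 1, which had 27 irradiated cells, it was -0.80. These values cover the shares of whole subclusters only. Fewer cells of a smaller group within a subcluster were not told apart from a lower level per cell. The planned test used the 9 lower genes, with a median of -2.53 weighted alike (-2.38 over all cells). Those 9 genes were picked as lower in these same counts, so their median is not separate support. Subcluster 2 did not share this (median -0.04, with 5 members higher and 3 lower), and Col2a1 had at most 5 UMIs per library in subclusters 0 and 2. Fewer tendon-gene cells among mesenchymal-like cells, the share on which a level within that class depends, were argued against too: cluster 14 held a share of the class 1.02 times that of the control, whereas of all cells it held 4.70% and 1.64%. An effect of radiation on cartilage formation stays open as untested, and a difference in the piece of tissue taken stays open.

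Irradiated cells of mesenchymal subclusters 1 to 4 held more UMIs than control cells. Doublets with macrophages, neutrophils or keratinocytes making up most of these cells were argued against. The median irradiated cell of each of these subclusters carried the markers of those types at no more than 0.00676 of their own level. Cells with immune or keratinocyte genes had already been placed in subclusters 5 and 6, so the test cannot decide on a smaller number of such doublets. Doublets of a pair of mesenchymal cells stay open, because the planned test of doublets left in was void. Only 2 irradiated cells of subclusters 1 to 4 had doublet scores in the lower part, against 304, 91, 192 and 30 control cells. A deeper irradiated library cannot be told apart, since the median fold over the other classes was 1.27, between the bounds set. An effect of radiation on cell content stays open as untested.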
